A study of Mus musculus with 6 samples.

How the data were processed

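RNA-seq of mouse LGE at embryonic day 16.5 was analysed from the processed tables, starting after read alignment and counting, which the authors had done. Per the labels' protocols, libraries were made from 1 ug of total RNA with an Illumina TruSeq RNA kit, a kind that does not mark strand. The submitters' processing notes name bcl2fastq 2.17.1.14, HISAT2, StringTie and edgeR and the builds GRCm38.p4 and mm10, without saying which step used which; the annotation release is not given in the sources used here. A full table of 29659 genes and a shorter table of 3726 genes were read. Every gene of the shorter table has a p under 0.05 in the authors' deposited table, which holds 3861 such genes.

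The deposited counts are whole numbers of reads or fragments per gene, per the file headers, with no normalisation. The deposited FPKM values are scaled by gene length and library total by the authors, per the file headers. The full table also gives the authors' log2 fold changes and the authors' p-values, raw and adjusted; its column names do not say which test produced them, and 126 genes have no p and 14938 no adjusted p. The authors' deposited table marks 122 genes as significant, 69 higher and 53 lower. In the full table the columns carry short names in place of the sample titles. They were tied to samples by the replicate number and the group word in the name, and for all 3726 genes of the shorter table, whose columns carry the titles, the counts and FPKM of each column were identical in both tables.

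The groups were control (3 libraries) and Zfhx3-CKO (3 libraries), as the labels name them. Within both groups the pairs of libraries differed by more than sampling noise (Pearson chi-square per gene 3.35 to 29.3, where sampling noise alone gives about 1), so each was kept as its own replicate. Pairs across the groups gave 27.1 to 37.4. Zfhx3-CKO libraries 2 and 3 (29.3) thus differed from each other by more than some pairs across the groups did. The main test was edgeR's quasi-likelihood test in R 4.3.3 (edgeR 4.0.16, limma 3.58.1) on the counts, with TMM factors (0.992 to 1.008), the filterByExpr filter at its default minimum count of 10 (16551 genes kept, 13108 left out), no covariate besides group, and Benjamini-Hochberg adjustment at 0.05. CPM values are counts scaled by the library total times its TMM factor, and errors are SD over 3 libraries. The SE of a log2 fold change was taken from the quasi-likelihood F statistic. A single gene with counts in only 1 group was given a bound against a floor of 3 counts over the group, and one with 1 to 3 counts a ratio with an exact (Clopper-Pearson) 95% interval; both cover counting error only. Library totals were 15938590 to 20311799 counts.

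Before the data were examined, 33 gene lists (striatal neuron classes, progenitors, other cell types, stress, signalling and sex-linked genes) were fixed, and 520 of their 526 genes were found in the table, with older symbols matched through RefSeq synonyms. Lists with at least 3 tested members were tested with limma's camera on log2 CPM (prior count 2) at a preset correlation of 0.01, with adjustment over the 33 lists. An estimated correlation and limma's fry were the alternatives. Genes named in the text followed a rule fixed at the same time: Zfhx3 and 15 other striatal genes whatever their values; the 10 largest folds in each direction among genes past the threshold, with groups that do not overlap and at least 1 CPM in the higher group; and up to 4 members with the smallest p of each list described. Predicted genes and pseudogenes were counted but not named; clone-style names, which the rule did not mention, were treated as having no symbol. Gene Ontology terms of the deposited table with 10 to 500 tested genes were tested with a one-sided Fisher's exact test against the 13263 tested genes with a term, with adjustment over both directions.

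Alternatives planned before the data were examined were a replicate block, DESeq2 (version 1.42.0), RLE factors, library totals only, no low-count filter, a strict filter of at least 5 CPM in at least 3 libraries, each library left out in turn, an added 2-fold threshold, and limma-trend on log2(FPKM + 1) for genes of at least 1 FPKM in 3 libraries. Settings planned only for normalised values did not apply, since counts were deposited. Chosen after the data were seen were the fit without Zfhx3-CKO libraries 1 and 3, the fit without X and Y genes, and the removal of GC and length trends, for which GC content came from the longest transcript per gene of GENCODE vM21 (GRCm38; 29552 of 29659 genes matched by ID). Coordinates are those of the deposited table. The replicate numbers did not pair the libraries, so the blocked fit served only as an alternative.

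The test was tried on simulated data with the mean, spread and totals of the Zfhx3-CKO against control comparison. Of 200 genes changed, 48, 49, 50 and 48 (at 1.5, 2, 4 and 8-fold) were among the 16327 that passed the filter. The test recovered 29.2% of genes changed 1.5-fold, 85.7% at 2-fold, 96% at 4-fold and 100% at 8-fold, with 7 calls among unchanged genes. The shifted list ranked first, with 0 of the unshifted lists called. Genes were simulated independently of each other, so the list result does not cover lists of correlated genes. The estimated correlation was 0.45 for the D1 list and 0.75 for the proliferation list. Figures were drawn with matplotlib 3.10.9. Which exons of Zfhx3 are deleted, and reads behind the counts, were not analysed here.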

Results

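The lateral ganglionic eminence (LGE) is the part of the embryonic ventral forebrain whose progenitors give rise to the projection neurons of the striatum. RNA was sequenced from mouse LGE at embryonic day 16.5 in 2 groups of 3 libraries. The control mice carried the Dlx5/6-Cre transgene, which expresses Cre recombinase in the ganglionic eminences. The Zfhx3-CKO mice carried it together with floxed copies of Zfhx3, which encodes a large zinc-finger and homeodomain transcription factor. The libraries held 15938590 to 16753355 counts in the control group and 18960574 to 20311799 in the Zfhx3-CKO group. The comparison addresses how the conditional loss of Zfhx3 changes gene expression in the LGE, in particular in D1-type striatal projection neurons, those with the dopamine D1 receptor. Nothing in the labels says that the replicates came from separate animals, so the p-values measure only the spread between these libraries, which may be technical. The control libraries held 5 to 9 counts of Xist, the RNA of the inactive X chromosome, and 4939 to 5451 counts over 4 Y-linked genes; the Zfhx3-CKO libraries held 55947 to 59631 and 5 to 8. Sex and genotype therefore split the 6 libraries in the same way, and no value here separates them.

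The targeted gene was examined first. Zfhx3 (ENSMUSG00000038872, chromosome 8, 107942644 to 108961630, plus strand, GRCm38) was measured at 123 ± 19.2 CPM (SD, n = 3) in the control libraries and at 95.1 ± 6.76 CPM (SD, n = 3) in the Zfhx3-CKO libraries, 77.3% of the control mean. All 3 Zfhx3-CKO values lay below all 3 control values. The exact two-sided permutation test gave p = 0.1, the smallest value that 3 against 3 libraries allow, and in edgeR's quasi-likelihood test the log2 fold change of -0.37 (SE 0.12) had a Benjamini-Hochberg adjusted p of 0.091. The difference did not pass the threshold of 0.05. The counts cover the whole gene and the labels do not give the deleted exons, so transcripts that lack them still add counts and the level is a limited check of the labels. The call changed without control library 3 (log2 fold change -0.50, adjusted p 0.0259). The related genes Zfhx2 and Zfhx4 were measured at log2 fold changes of 0.28 and 0.27 (adjusted p 0.173 and 0.237), and the list of 3 Zfhx genes had a camera adjusted p of 0.9; adjusted over the list alone, 1 of the 3 genes (Zfhx3) passed.

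In the Zfhx3-CKO LGE, 3 of 14 tested genes of D1-type striatal projection neurons fell, and 6 of 11 genes of D2-type striatal projection neurons rose. Ebf1, a transcription factor of differentiating D1-type neurons (ENSMUSG00000057098, chromosome 11, 44617317 to 45008091), fell 7.43-fold, from 239 ± 27.6 to 32.2 ± 6.81 CPM (SD, n = 3 each), a log2 fold change of -2.89 (SE 0.16, adjusted p 5.17e-05). Isl1, a LIM-homeodomain factor of the same neurons, fell from 160 ± 26 to 67 ± 11.3 CPM (log2 fold change -1.26, SE 0.15, adjusted p 0.00302). Sox8 fell from 169 ± 4.72 to 78.3 ± 10.5 CPM (log2 fold change -1.11, SE 0.10, adjusted p 0.000624). The dopamine D1 receptor gene Drd1 was measured at 19.6 ± 2.3 and 12.8 ± 5.18 CPM (log2 fold change -0.61, adjusted p 0.196), and Tac1, the substance P precursor, at 32.5 ± 4.46 and 33.2 ± 12.9 CPM (log2 fold change 0.03, adjusted p 0.959), so neither passed; without Zfhx3-CKO library 3, Drd1 passed (log2 fold change -0.92, adjusted p 0.0296). The other 11 D1 genes did not pass (Sfxn1, with the next smallest p, had a log2 fold change of -0.32 and an adjusted p of 0.0705); adjusted over the list alone, 6 of the 14 were lower and 1 was higher. The list had a median log2 fold change of -0.48 and a camera adjusted p of 0.00361 with the preset correlation, and an adjusted p of 0.971 with an estimated correlation. DESeq2 and the fit with no low-count filter each called 5 D1 genes lower, and without Zfhx3-CKO library 3, 8 passed as lower; without Zfhx3-CKO libraries 1 and 3, a fit chosen after the data were seen, 7 did. Relative to the control mean, the D1 list median stood at -0.58, -0.73 and -0.11 (log2) in Zfhx3-CKO libraries 1, 2 and 3, where the median of a list of cortical excitatory neuron genes stood at 1.58, 0.04 and 1.69. In control libraries 1, 2 and 3 the D1 list median stood at 0.14, 0.05 and -0.15. Zfhx3-CKO library 3 thus lay above control library 3, and the groups overlapped on this median.

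Of the 11 D2 genes, 6 rose and 5 did not pass. Sp9, a zinc-finger factor needed for D2-type neurons (ENSMUSG00000068859, chromosome 2, 73271925 to 73284706), rose from 186 ± 27.8 to 374 ± 32.9 CPM (log2 fold change 1.01, SE 0.11, adjusted p 0.00244). Six3, a homeodomain factor of the same lineage, rose from 116 ± 8.32 to 175 ± 8.84 CPM (log2 fold change 0.60, adjusted p 0.00395). The adenosine receptor gene Adora2a rose 2.16-fold, from 32.6 ± 3.38 to 70.4 ± 11.9 CPM (adjusted p 0.00326), and the kainate receptor gene Grik3 from 275 ± 31.3 to 427 ± 29 CPM (adjusted p 0.00771). Penk, the enkephalin precursor, rose from 4.63 ± 0.81 to 13.2 ± 4.91 CPM (log2 fold change 1.51, SE 0.27, adjusted p 0.0158), and the dopamine D2 receptor gene Drd2 from 24.2 ± 1.5 to 39.1 ± 7.69 CPM (log2 fold change 0.69, SE 0.14, adjusted p 0.0274). The list median was 0.63, with a camera adjusted p of 0.000446 and an adjusted p of 0.146 with an estimated correlation; adjusted over the list alone, 8 genes were higher, and with the replicate number as a block 3 were. The D2 list median stood at 0.63, 0.55 and 0.74 above the control mean in Zfhx3-CKO libraries 1, 2 and 3. The calls of Penk and Drd2 were lost when single control libraries were left out, each of the 3 in turn, and that of Drd2 also without Zfhx3-CKO library 1 (highest adjusted p 0.0824 and 0.119).

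**Figure D1:**
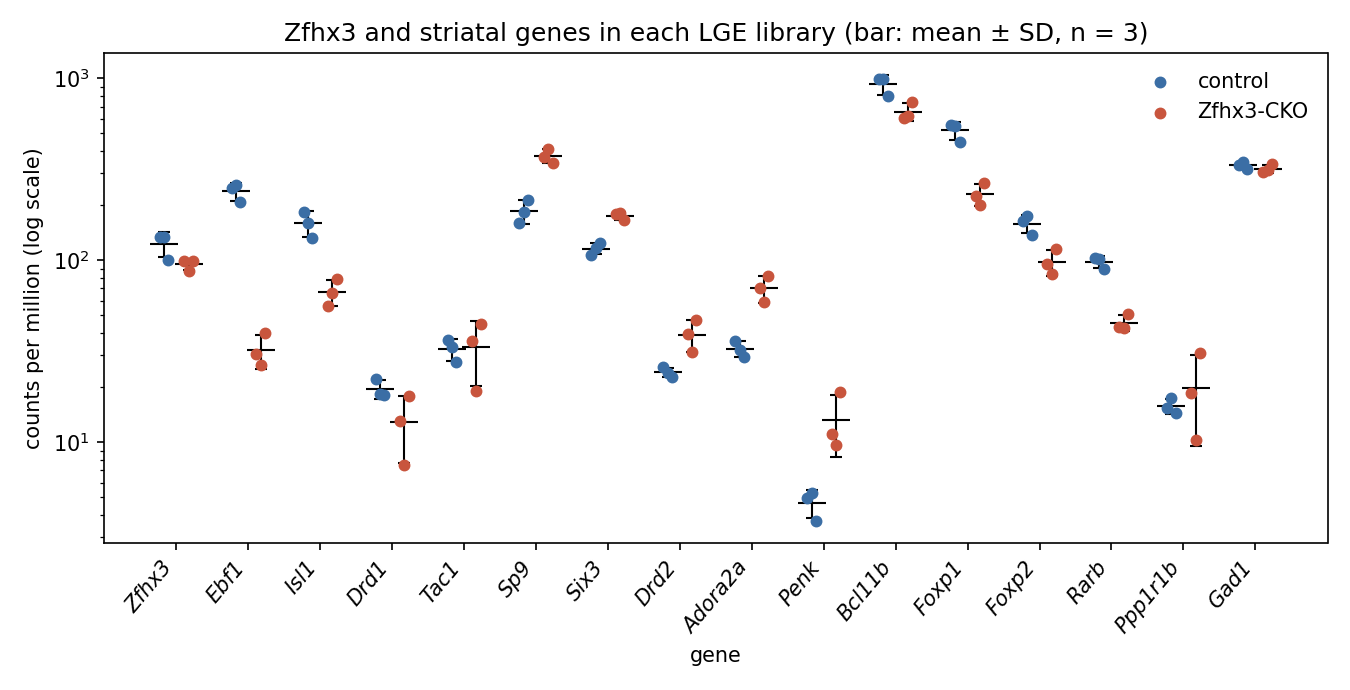
CPM (log axis) of Zfhx3 and 15 striatal genes in the 3 control and 3 Zfhx3-CKO libraries; points are libraries, horizontal bars are means and error bars the SD (n = 3). For Ebf1 and Isl1 every Zfhx3-CKO library lies below every control library, and for Sp9, Six3, Drd2, Adora2a and Penk every one lies above.

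Of 27 tested genes shared by both classes of striatal projection neuron, or by their differentiation, 10 fell and 17 did not pass. Ikzf1, an Ikaros-family zinc-finger factor, fell from 104 ± 2.59 to 14.9 ± 2.87 CPM (log2 fold change -2.80, SE 0.13, adjusted p 1.75e-05). The retinoic acid receptor gene Rarb fell from 97.8 ± 7.71 to 45.3 ± 4.51 CPM (log2 fold change -1.11, adjusted p 0.000622), Foxo1 from 61.3 ± 4.36 to 28.1 ± 2.66 CPM (adjusted p 0.000624) and the forkhead factor Foxp1 from 518 ± 60.6 to 230.3 ± 31.8 CPM (log2 fold change -1.17, adjusted p 0.00144). Foxp2 (log2 fold change -0.69, adjusted p 0.0177) and Bcl11b, also known as Ctip2 (log2 fold change -0.50, adjusted p 0.0323), fell by less. Ppp1r1b, which encodes DARPP-32, and Gad1, a GABA-synthesising enzyme, had log2 fold changes of 0.34 and -0.06 (adjusted p 0.568 and 0.602). The list median was -0.09, the camera adjusted p was 0.00477, and the adjusted p was 0.972 with an estimated correlation; adjusted over the list alone, 10 genes were lower, and with the replicate number as a block 6 were. The list median stood at -0.13, -0.58 and 0.14 in Zfhx3-CKO libraries 1, 2 and 3 and at 0.06, 0.06 and -0.13 in the control libraries, so that Zfhx3-CKO library 3 lay above every control library. The camera adjusted p was 0.391 without Zfhx3-CKO library 2, where 2 members were higher, and the number of lower genes was 5 without control library 1, 5 without control library 2 and 6 without Zfhx3-CKO library 1. In those 3 settings the calls of Foxp2 and Bcl11b were lost (highest adjusted p 0.0991 and 0.149).

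Of the 13 retinoid genes, 9 did not pass and 4 fell: Rarb, Stra6, the retinol transporter (log2 fold change -1.07, adjusted p 0.0044), Zfp503, a zinc-finger factor (log2 fold change -0.60, adjusted p 0.00526) and Rxrg, a retinoid X receptor (log2 fold change -0.89, adjusted p 0.0107). Adjusted over the list alone, 6 were lower and 2 higher, the same counts as with DESeq2. The retinoid list shares 3 genes with the projection neuron list, Rarb, Zfp503 and Rxrg, which were already counted as lower there. It did not pass as a whole (camera adjusted p 0.0809). The call of Rxrg was lost without control library 1, control library 2 or Zfhx3-CKO library 1 (highest adjusted p 0.0731).

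Of 29 LGE progenitor genes 6 rose and 23 did not pass. Among the 6 were the Notch target Hes1, from 6.17 ± 0.578 to 14 ± 1.2 CPM (log2 fold change 1.18, SE 0.14, adjusted p 0.00311), the Notch ligand Dll3 (log2 fold change 1.00, adjusted p 0.00644), Sox3, a factor of neural progenitors (log2 fold change 0.98, adjusted p 0.0126), and the receptor Notch1 (log2 fold change 0.48, adjusted p 0.0307). Sox3 lies on the X chromosome, and the groups differ in sex. Of 33 proliferation genes 6 rose and 27 did not pass. Among the 6 were Mki67, which marks cycling cells, from 519 ± 35.2 to 793 ± 109 CPM (log2 fold change 0.61, SE 0.10, adjusted p 0.0124), the cyclin gene Ccnd1 (log2 fold change 0.49, adjusted p 0.0142), Cenpf, a kinetochore protein gene (log2 fold change 0.47, adjusted p 0.0294), and Hmgb2 (log2 fold change 0.51, adjusted p 0.0298). Adjusted over the list alone, 8 progenitor and 12 proliferation genes were higher. DESeq2 called 9 and 10 higher, the fit with no low-count filter 10 and 13, and the fit with the replicate number as a block 2 and 1; limma-trend on FPKM called 2 proliferation genes. The camera adjusted p was 0.000787 for the progenitor list and 5.77e-06 for the proliferation list, and with an estimated correlation the adjusted p was 0.972 and 0.971. Relative to the control mean, the progenitor list median stood at 0.30, 0.41 and 0.02 (log2) in Zfhx3-CKO libraries 1, 2 and 3 and the proliferation list median at 0.35, 0.49 and 0.04. Zfhx3-CKO library 3 lay below control library 3 for both lists (0.15 and 0.09). In Zfhx3-CKO libraries 1, 2 and 3 and control library 3, the synaptic maturation list stood at -0.14, -0.39, 0.30 and -0.13, and the list shared by projection neurons at -0.13, -0.58, 0.14 and -0.13. Without Zfhx3-CKO library 3 the counts of higher genes were 12 progenitor and 26 proliferation genes, without Zfhx3-CKO library 1 they were 2 and 0, without control library 1 they were 2 and 0, and without control library 2 they were 2 and 2; without control library 3, 2 proliferation genes were higher. Without Zfhx3-CKO libraries 1 and 3 the counts were 13 and 26. With GC and length trends removed, an alternative chosen after the data were seen, 2 progenitor genes were higher, and the calls of Sox3, Notch1 and Cenpf were lost. Without single libraries, the highest adjusted p was 0.076 for Sox3, 0.133 for Notch1, 0.0735 for Mki67, 0.0838 for Ccnd1, 0.111 for Cenpf and 0.131 for Hmgb2.

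Markers of other cells that the dissected pieces could hold were also compared. The list of 17 cortical excitatory neuron genes had a median log2 fold change of 1.37 (camera adjusted p 0.00107, adjusted p 0.971 with an estimated correlation), and its median stood at 1.58, 0.04 and 1.69 above the control mean in Zfhx3-CKO libraries 1, 2 and 3. Without libraries 1 and 3, which leaves a lone Zfhx3-CKO library assumed to vary like the controls, the list's adjusted p was 0.947. Neurod2, a factor of cortical projection neurons, was at 8.31 ± 0.29 CPM in the controls and at 39, 9.68 and 69.4 CPM in the 3 Zfhx3-CKO libraries (adjusted p 0.0519), and Neurod6 at 6.28 ± 0.813 CPM and at 26.9, 6.29 and 46.2 CPM (adjusted p 0.0658). Lhx2 (log2 fold change 0.85, adjusted p 0.0139) and Bhlhe22 (log2 fold change 2.92, adjusted p 0.0401) rose, and the other 15 genes did not pass; adjusted over the list alone, 13 were higher and 1 was lower, and DESeq2 called 5 higher. Both calls were lost without control library 1, control library 2 or Zfhx3-CKO library 1, and that of Bhlhe22 also without control library 3 (highest adjusted p 0.0793 and 0.147). Without library 2, Neurod2 and Neurod6 passed (adjusted p 0.000259 and 0.000446). In the fit without libraries 1 and 3, chosen after the data were seen, 863 genes were higher and 856 lower, 10 of the 78 called genes that are named lost their call, and Tac1 was lower (log2 fold change -0.76, adjusted p 0.0235).

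Of 23 medial ganglionic eminence genes 4 rose and 1 fell: Nkx2-1, which specifies that region, had a log2 fold change of 0.90 (adjusted p 0.0276), Lhx8 of 1.35 (adjusted p 0.0123) and the chemokine receptor gene Cxcr4 of -0.84 (adjusted p 0.00326). Nkx6-2 rose from 2.39 ± 0.367 to 5.27 ± 0.818 CPM (adjusted p 0.0176). The list median stood at 0.38, 0.02 and 0.56 above the control mean in Zfhx3-CKO libraries 1, 2 and 3, where the cortical excitatory list stood at 1.58, 0.04 and 1.69. The list did not pass (camera adjusted p 0.0694), but passed with no low-count filter (0.0156), without Zfhx3-CKO library 1 (0.0256) and without Zfhx3-CKO library 2 (0.0057); adjusted over the list alone, 5 were higher and 1 lower. Without single libraries the calls of Lhx8 and Nkx2-1 (each control library) and Nkx6-2 (control libraries 1 and 2 and Zfhx3-CKO library 1) were lost, with highest adjusted p of 0.0743, 0.134 and 0.0979. The endothelial and pericyte list had a median of 0.26 and a camera adjusted p of 0.0312 (adjusted p 0.971 with an estimated correlation), yet none of its 19 genes passed, over all genes in edgeR's test or adjusted over the list alone; 5 were higher at an unadjusted p under 0.05, and 2 passed with DESeq2. Pecam1 came nearest (log2 fold change 0.43, adjusted p 0.0755). That list did not pass without control library 2, control library 3 or Zfhx3-CKO library 3 (0.0714, 0.0586 and 0.0596) or with the strict low-count filter (0.0545).

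**Figure D2:**
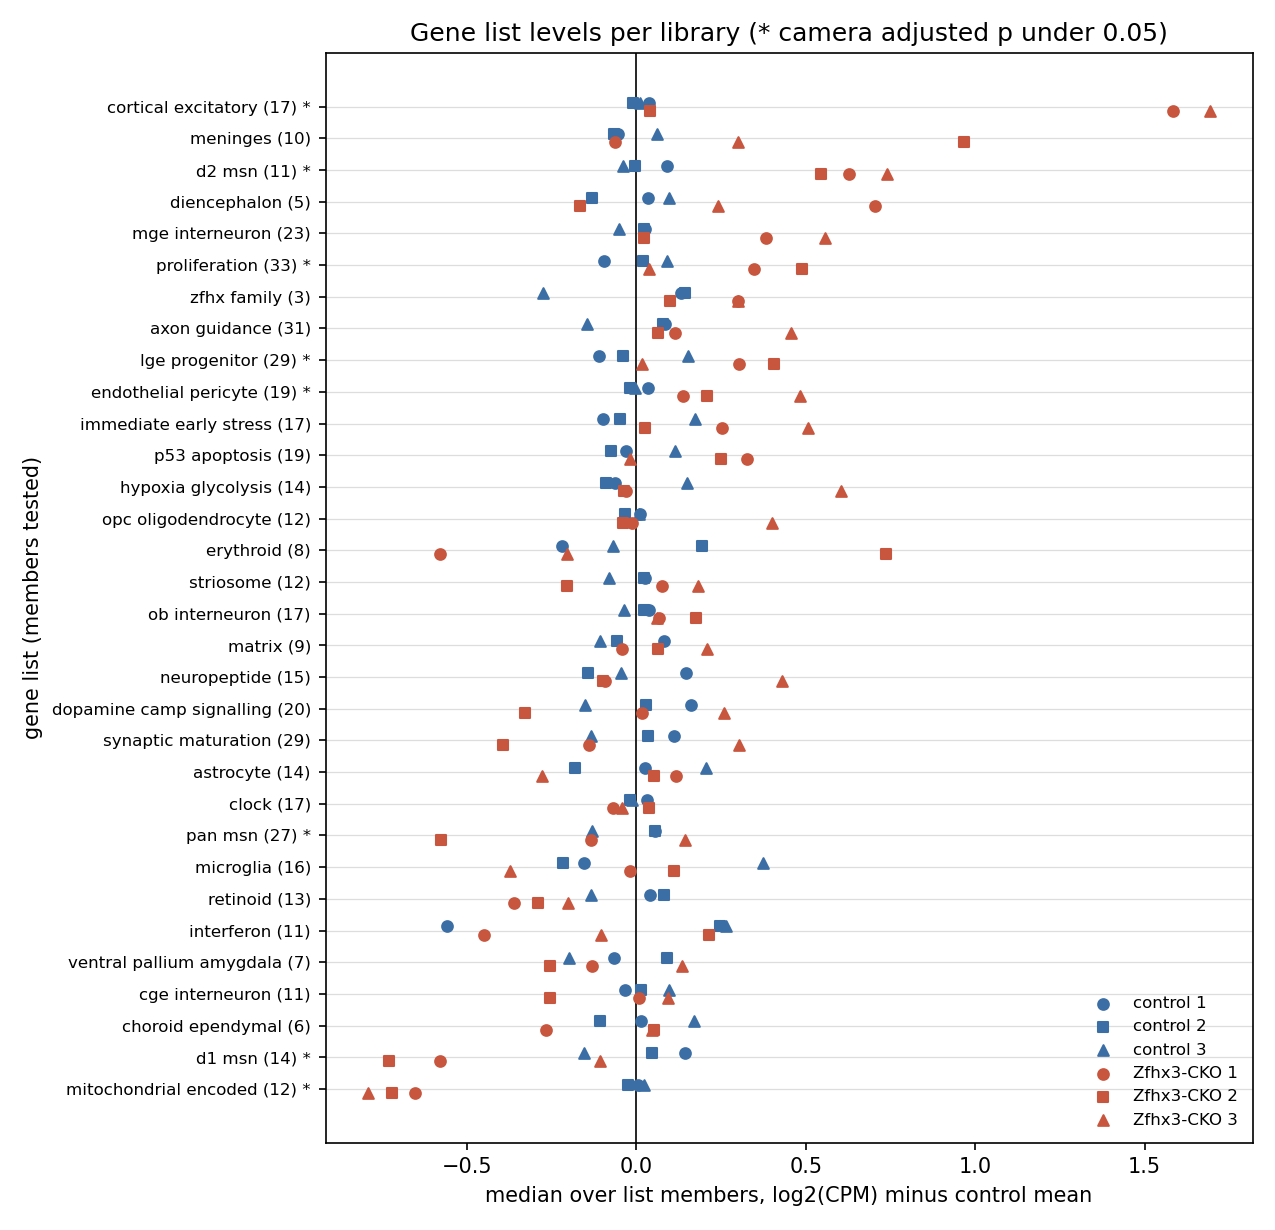
Median over the members of each fixed gene list of log2 CPM minus the control mean, 1 point per library (x axis, log2 units); the number of tested members stands in parentheses, asterisks mark lists with a camera adjusted p under 0.05 at the preset correlation, and the sex-linked list is left out. The cortical excitatory list stood at 1.58 and 1.69 in Zfhx3-CKO libraries 1 and 3 and at 0.04 in library 2.

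Of 31 axon guidance genes 6 rose and 2 fell, and the list as a whole did not pass (camera adjusted p 0.165), but passed without Zfhx3-CKO library 2 (0.0242). The guidance receptor gene Robo3 rose from 2.63 ± 0.447 to 13.2 ± 4.62 CPM (log2 fold change 2.33, SE 0.29, adjusted p 0.00367; 1.65 without Zfhx3-CKO libraries 1 and 3 and 1.05 with limma-trend on FPKM). The ligand genes Ntn1 and Slit1 rose (log2 fold change 0.72 and 0.45, adjusted p 0.00637 and 0.00921), and the ephrin receptor gene Ephb1 fell (log2 fold change -0.59, adjusted p 0.00943). The call of Ephb1 was lost without control library 1, control library 2 or Zfhx3-CKO library 1 (highest adjusted p 0.067), and that of Slit1 with GC and length trends removed. Adjusted over the list alone, 7 were higher and 3 lower. In a one-sided Fisher's exact test of 1911 Gene Ontology process terms in each direction, axon guidance held 16 of the genes called higher where 4.86 were expected (adjusted p 0.0509). The 1 term that passed, viral transcription (adjusted p 0.0376), held 8 called genes, all Rpl21 or copies of it, which can share reads.

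The groups also parted on sex-linked and mitochondrial transcripts. All 5 sex-linked genes passed, 1 higher and 4 lower, over all genes and adjusted over the list alone (camera adjusted p 0.000241, adjusted p 0.146 with an estimated correlation). Of 12 mitochondrially encoded genes 11 fell and 1 did not pass (camera adjusted p 2.59e-12, adjusted p 0.0564 with an estimated correlation), and adjusted over the list alone all 12 were lower. Mitochondrial counts made up 2.31% ± 0.0389 of the control and 1.48% ± 0.0327 of the Zfhx3-CKO totals (SD, n = 3 each). Other measures of the libraries also differed between the groups: genes of the rRNA biotype made up 0.0295% ± 0.0134 and 0.00485% ± 0.000304 of the totals, Lars2 0.0457% ± 0.0295 and 0.0058% ± 0.000723, and the 10 genes with the most counts in each library 4.07% ± 0.1 and 3.44% ± 0.0244 (SD, n = 3 each). For each of the 3, every control library lay above every Zfhx3-CKO library, which chance gives for 10% of measures in either direction. The haemoglobin share, the pseudogene share, the number of genes with counts and the TMM factors overlapped between the groups. These measures need not be independent of each other. The complex I genes mt-Nd1 (log2 fold change -0.92, adjusted p 0.000656) and mt-Nd2 (log2 fold change -0.77, adjusted p 0.00081) fell, as did mt-Atp6 (log2 fold change -1.02, adjusted p 0.000699) and mt-Nd6 (log2 fold change -1.06, adjusted p 0.000329); the library kit does not mark strand, so mt-Nd6 reads cannot be told from those of the opposite strand.

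Over all genes tested, 640 rose and 578 fell among 16551 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), of which 180 and 176 changed at least 2-fold. The authors' deposited table gives an adjusted p under 0.05 to 1011 higher and 718 lower genes; 601 and 519 of the genes called here are among them, in the same direction. The increases and decreases named next leave out predicted genes, pseudogenes and clone-style names, of which 25 had a larger increase than the smallest of the 10 named and 1 a larger decrease. Among the 10 named increases Xist had a log2 fold change of 12.61 (SE 0.14), below 1 of the genes left out, and it overlaps an antisense gene. The class I major histocompatibility gene H2-T23 came next among the named genes, below 7 of those left out, at 45.1-fold (95% exact counting interval 15.2 to 221, from 3 counts in the controls), with Ibsp at 17.3-fold (5.64 to 86 from 3 counts) and H2-T24 at 11.6-fold (adjusted p 0.000624). H2-T23 and H2-T24 have close paralogs, so their levels are uncertain. Ppm1j, Bhlhe22, Zfp97, AI506816, Endog and Rpl21 lay 7.6, 7.56, 6.28, 6.2, 5.96 and 5.84-fold higher; Rpl21 can share reads with pseudogene copies, so its level is uncertain too. Single libraries ended the calls of Ibsp, Ppm1j, Bhlhe22 and Zfp97 (highest adjusted p 0.0743, 0.159, 0.147 and 0.184), each of them without control library 1, control library 2 or Zfhx3-CKO library 1, with Bhlhe22 also lost without control library 3 and Zfp97 without Zfhx3-CKO library 3. Some of these folds rested on single libraries. The log2 fold change of Ppm1j was 2.93 and became 4.43 without control library 3, that of Zfp97 was 2.65 and became 3.96 without the same library, and that of Bhlhe22 was 2.92 and became 2.08 without Zfhx3-CKO library 3. Ibsp moved from 3.96 to 4.82 without control library 1 and H2-T23 from 5.35 to 6.24 without control library 2. Without Zfhx3-CKO libraries 1 and 3, Ppm1j stood at 1.73 and Bhlhe22 at 0.91 (adjusted p 0.162 and 0.228). The scale log2(FPKM + 1) shrinks folds of genes at low levels, and limma-trend on it gave 7.34 for Xist, 1.42 for H2-T24, 2.03 for AI506816 and 1.54 for Endog.

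Among the 10 named decreases 4 were Y-linked: Ddx3y (2412-fold, interval 667 to 19924), Uty (824-fold, interval 282 to 3999), Eif2s3y and Kdm5d (log2 fold change -10.26 and -9.17, with -10.93 for Eif2s3y without Zfhx3-CKO library 3 and -9.91 for Kdm5d without Zfhx3-CKO library 1). All 3 Zfhx3-CKO counts of Uty lay in library 1. Without single libraries the log2 fold change of Uty, -9.50, ranged from -12.52 to -8.97. The other 6 named decreases are genes typical of oocytes, with no counts in any Zfhx3-CKO library. Against a floor of 3 counts over the group, Fbxw28 was at least 159-fold lower, Fbxw24 at least 129-fold, Fbxw14 at least 112-fold, Fbxw15 at least 100.1-fold, Nlrp14 at least 81.8-fold and C87977 at least 69.4-fold. The Fbxw genes are near-identical neighbours that can share reads, so the split between them is uncertain. Intervals and floors cover counting error only. Without control library 1 the counts of higher and lower genes were 158 and 131, without control library 2 156 and 144, without control library 3 415 and 311, without Zfhx3-CKO library 1 221 and 180, and without Zfhx3-CKO library 3 1082 and 1014. GC content went with the fold change (Spearman's rho 0.28 across genes, which are not independent replicates), with medians of -0.17 and 0.17 in the lowest and highest of 10 equal groups of genes ordered by GC content. With the X and Y chromosomes left out, 607 genes were higher and 550 lower.

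**Figure D3:**
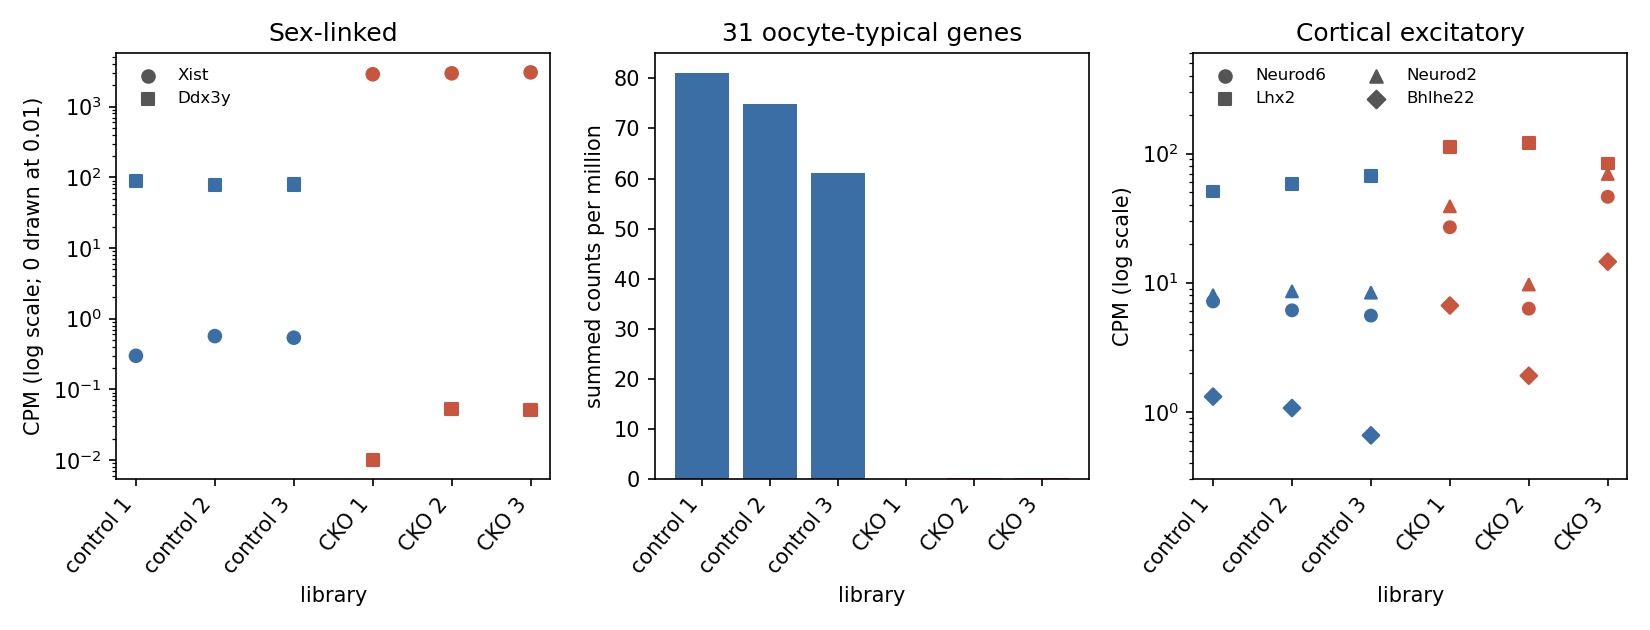
Left, Xist and Ddx3y in CPM (log axis, 0 drawn at 0.01); middle, summed CPM (of library totals) of 31 oocyte-typical genes (bars start at 0); right, 4 cortical excitatory genes in CPM (log axis); each point or bar is 1 library, control in blue and Zfhx3-CKO in red. The oocyte-typical genes were picked among called genes, which favours a gap. They sum to 61.2 to 81.0 CPM in the controls and to at most 0.305 CPM in the Zfhx3-CKO libraries.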

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

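The fits without Zfhx3-CKO libraries 1 and 3, without X and Y genes, and with GC and length trends removed were chosen after the data were seen. Against 640 higher and 578 lower genes, the counts were 176 and 136 with the replicate number as a block, 1021 and 755 with DESeq2, 1075 and 786 with no low-count filter, and 180 and 176 with the added 2-fold threshold. Leaving out each library in turn gave 156 to 1082 higher and 131 to 1014 lower genes. RLE factors, library totals, the strict filter and FPKM kept both counts within 1.5 times. So did the fits without X and Y genes and with GC and length trends removed. In some of these fits the called genes changed more than the counts. Of the 1218 calls, RLE factors kept 1194 and FPKM, with 13896 genes tested, kept 836. With GC and length trends removed, 839 were kept and 1142 genes were called. Replicate numbers did not pair the libraries: the correlations of same-numbered deviations were -0.03, -0.08 and -0.25. The Zfhx3 log2 fold change of -0.37 was -0.36 with DESeq2 (adjusted p 0.0489), -0.36 with no low-count filter (0.0308) and -0.55 with GC and length trends removed (0.00614), each past the threshold. Without single libraries it lay between -0.50 and -0.29. Of 33 gene lists, 9 passed at the preset correlation, 0 with an estimated correlation (3 at an unadjusted p under 0.05) and 3 with fry. Without Zfhx3-CKO libraries 1 and 3, Tac1 was lower (log2 fold change -0.76) and the erythroid list turned direction (adjusted p 0.00253). The causes of these changes were not tested.

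Of 148 named genes 78 were called, and 40 of them passed in every alternative fixed before the data were examined in which they were tested. The block ended 31 of the 78 calls, and single left-out libraries ended 35, 33 and 15 (control 1, 2 and 3) and 29, 5 and 3 (Zfhx3-CKO 1, 2 and 3). No called gene reversed. A change of sign with neither value past the threshold was not counted as a reversal, a choice made after the changes were seen. It concerned 10 genes and 17 lists, in 15 gene and 49 list settings. With 3 libraries per group, the test recovered 29.2% of simulated 1.5-fold changes between Zfhx3-CKO and control, so changes of that size often went undetected.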

Other observations

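The tests of expression in the control tissue, neuron share, sex and chromosome segments, the count by gene family of oocyte markers and the interval of the odds ratio were chosen only after the results were seen.

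Among glial genes, the purinergic receptor gene P2ry12 of microglia fell from 70.5 ± 17.8 to 20.2 ± 5.66 CPM (log2 fold change -1.80, edgeR adjusted p 0.00407). The lysozyme gene Lyz2 rose (log2 fold change 1.46, adjusted p 0.022) and Ptprc, the leukocyte antigen CD45, fell (log2 fold change -0.68, adjusted p 0.0356). The 16 microglial genes as a list did not pass (camera adjusted p 0.839; adjusted over the list alone, 2 higher and 2 lower). The call of Lyz2 was lost without control library 1, control library 2 or Zfhx3-CKO library 1, and that of Ptprc without those, control library 3 or Zfhx3-CKO library 2 (highest adjusted p 0.115 and 0.148). Gfap, an intermediate filament of astrocytes, fell (log2 fold change -2.47, adjusted p 0.0118; 0.0686 at most without control library 1 or Zfhx3-CKO library 1) in an astrocyte list that did not pass (0.931). Of 19 p53 and apoptosis genes 4 rose and 2 fell (camera adjusted p 0.174; 0.0499 without control library 3), 7 and 3 adjusted over the list alone. The cell-cycle inhibitor Cdkn1a (log2 fold change 0.68, adjusted p 0.0104) and Phlda3 (log2 fold change 1.63, adjusted p 0.0112) rose, and both calls were lost without control library 1 or 2 (highest adjusted p 0.0696 and 0.0797).

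Among signalling genes, Rgs2, a regulator of G-protein signalling, fell from 96.9 ± 6.66 to 35.0 ± 5.44 CPM (log2 fold change -1.47, adjusted p 0.000438), and it stayed past the threshold without any single library. The cannabinoid receptor gene Cnr1 (log2 fold change -1.65, adjusted p 0.00802) and the neurofilament gene Nefl (log2 fold change -1.51, adjusted p 0.00892) fell; Cnr1 was lost without control library 1 or 2 (highest adjusted p 0.0575) and Nefl without control library 2 (0.0587), and without Zfhx3-CKO libraries 1 and 3 the log2 fold changes were -2.32 and -2.15. Cnr1 also belongs to the shared projection neuron list, which passed at the preset correlation (camera adjusted p 0.00477) but not with an estimated correlation (0.972). The other lists of these genes did not pass: dopamine and cAMP signalling (camera adjusted p 0.931), caudal ganglionic eminence (0.794) and synaptic maturation (0.664; 0.00333 without Zfhx3-CKO library 3). Tshz1, a zinc-finger factor, rose (log2 fold change 0.57, adjusted p 0.00526) in the striosome (0.931) and olfactory bulb interneuron (0.499) lists. The remaining lists did not pass either: matrix (0.803), ventral pallium and amygdala (0.931), diencephalon (0.931), oligodendrocyte lineage (0.433), meninges (0.208; 0.0337 without Zfhx3-CKO library 1), erythroid (0.931), choroid plexus (0.931), neuropeptide (0.839), immediate early and stress (0.252; 0.0393 without Zfhx3-CKO library 2), hypoxia (0.41), interferon (0.931) and clock (0.931). In edgeR's test the matrix, oligodendrocyte, neuropeptide, immediate early and clock lists each held 1 higher gene, striosome 2 higher and 1 lower, and olfactory bulb 3 higher. Adjusted over the list alone these counts were the same, except 0 for immediate early, 2 for clock and 3 higher for meninges. Several of these genes depended on single libraries. With each library left out in turn, Calb1 and Olig2 lost their call in 4 fits. Hspb1, Per2, Scgn and Vax1 lost it in 5, and Tshz1 in 0. No gene of the meninges, hypoxia, choroid plexus, ventral pallium, interferon, diencephalon or erythroid lists passed over all genes. At an unadjusted p under 0.05, 4 meninges, 4 hypoxia and 1 choroid plexus genes were higher, ventral pallium and interferon each had 1 higher and 1 lower, and the diencephalon and erythroid lists had 0. DESeq2 called 2 meninges and 1 hypoxia genes and 0 in the other 5 lists. It called 3 neuropeptide and 2 clock genes higher, 2 dopamine and cAMP signalling, 2 microglial and 1 synaptic maturation genes higher, and 2 striosome genes lower. Median, mean and test differed in sign for the striosome, ventral pallium, erythroid, synaptic maturation, dopamine signalling and clock lists.

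The 31 called genes typical of oocytes summed to 81.0, 74.8 and 61.2 CPM in the control libraries and to 0.0492, 0.211 and 0.305 CPM in the Zfhx3-CKO libraries, with 24 of them at 0 counts there. If oocyte RNA had reached the controls, further oocyte markers should be higher there: of 30 detected markers not examined before, 28 were (93.3%), but 14 belong to families of called genes and can share their reads, and Spo11, Nlrp4c and Zbed3 were nearly level (7 and 7 counts, 3 and 3 counts, 35.5 and 35.0 CPM). With those families left out and every other family counted once, 10 of 12 were higher, as were 10 of 13 markers already examined, while Zar1, Mos and Ooep were not (0.159, 0.222 and 1.23 CPM against 0.273, 0.233 and 1.82). Expression in the control tissue itself, ended by the knockout or absent in the other sex, would give a gap between the groups just as well. The gap was 200.8-fold between the lowest control and the highest Zfhx3-CKO library. It decides nothing, since the 31 genes were picked among called genes. These explanations cannot be told apart, because every control library holds at least 1015 counts of these genes and every Zfhx3-CKO library at most 6.

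Lower D1-type and higher D2-type genes could come from GC bias between the groups, from fewer striatal projection neurons in the Zfhx3-CKO pieces, or from sex. With GC and length trends removed, the 9 called D1 and D2 genes kept 85.6% of their median absolute log2 fold change (82.0% to 105.7% for single genes) and all 9 passed, which argues against GC bias as the whole cause. Fewer projection neurons of both classes alike would lower D2 genes too. The D2 list median instead lay 0.45 (log2) higher in the lowest Zfhx3-CKO library than in the highest control library. That argues against a loss of both classes alike as the cause of the higher D2 genes. The value is part of the pattern itself, so it does not bear on other shifts in cell make-up. For the D1 genes fewer neurons and other causes cannot be told apart: the list shared by both classes had a median of -0.0895, and its range over the Zfhx3-CKO libraries (-0.58 to 0.14) overlaps that of the D1 list (-0.73 to -0.11). Sex stays open, since each group holds 1 sex. The 1156 called genes outside the X and Y chromosomes do not separate sex from genotype. Library totals and the mitochondrial share also split the libraries by group, so whatever lies behind those differences stays open too. An effect of the genotype remains a hypothesis that cannot be told apart from sex or from those differences.

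Some large changes lay close together, on chromosomes 17 and 12. Of 12 tested histocompatibility genes with H2 names on chromosome 17, H2-T22, H2-T23 and H2-T24 were higher, H2-DMb2 was lower (log2 fold change -2.50) and 8 did not pass; H2-T22 (log2 fold change 2.46) and H2-DMb2 were picked after their values were seen. A segment carried along with the floxed allele may add calls near Zfhx3, but 6.03% of tested genes within 20 Mb passed (21 of 348) against 7.20% elsewhere on the autosomes. The odds ratio was 0.83 (95% interval 0.50 to 1.29, Fisher's exact p 0.462, two-sided), an interval that leaves a small excess open. Strain variants away from Zfhx3 may explain the 25% of genes called between 15 and 25 Mb of chromosome 12 (15 of 60), but that segment was picked because it showed the pattern, so its test decides nothing.

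The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split was the 1 with as many calls (640 higher and 578 lower genes), and the highest count of any other split was 1. Each other split mixes libraries of both groups, so any difference between the groups, sex included, adds to the spread within each side. Few calls would follow there whatever the cause, so the comparison decides nothing.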
